A study of Mus musculus with 28 samples.

How the data were processed

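The series holds 28 mouse samples: 14 RNA-seq libraries and 14 ChIP-seq, MNase-seq or input libraries. The cell types are cultured germline stem cells (GS), isolated THY1-positive undifferentiated spermatogonia (THY1), pachytene spermatocytes (PS) and round spermatids (RS). GS cells are of CD1 and C57BL/6 mixed strain and the other cells of C57BL/6, per the labels. Per the labels' protocols, PS and RS came from adult mice by BSA gradient, and the RNA libraries were built with the TruSeq RNA kit, version 2.

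For the RNA-seq, the deposited tables give whole reads per transcript (counts) and, computed by the authors, the RPKM of each transcript, which is reads scaled by transcript length and library size. The submitters' processing notes name TopHat2 2.0.9 and Bowtie 1.0.0 with the builds mm10 and mm9 for the first batch and mm10 for the later one. Coordinates in the tables are mm10. Which tool made the counts, and how, is not given in the sources used here. For the ChIP-seq and MNase-seq, the deposited peak lists carry, per the file headers, the pileup signal at the summit in reads, the fold ratio of the summit over the local background, and the -log10 p and -log10 q of the peak caller. The notes name MACS2 without a version. The control library and the threshold used for peak calling are not given in the sources used here.

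Transcript counts were summed per gene symbol. The GS, PS and RS tables list 31213 transcripts under 23471 symbols and those of THY1 list 26049 under 23335, with 23197 symbols shared. A symbol in 138 entries of the THY1 tables names several genes, which were kept as they are. Reads that fit near-identical gene copies cannot be assigned to 1 copy, so values of such copies are shared. Groups came from the labels, with 2 libraries in each of 7 RNA groups. The labels do not state that replicates are separate animals, so p-values of edgeR, DESeq2 and limma measure the spread between these libraries only. At the preset correlation camera also takes genes as nearly independent. Fisher's exact and Mantel-Haenszel tests count genes or peaks as units, so their p-values and intervals hold no spread between libraries. Bootstrap intervals resample genes and hold none either. Floors and the intervals of peak shares cover counting error only, since reads are PCR products without molecular identifiers.

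Calls used edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM factors, the quasi-likelihood F test (two-sided) and Benjamini-Hochberg adjusted p below 0.05. PS and RS were fitted together (8 libraries, 17287 genes, 4 residual degrees of freedom, common biological coefficient of variation 0.134). THY1 was fitted alone (4 libraries, 14801 genes, 2 residual degrees of freedom, 0.086). The PS minus THY1 difference used all 12 knockout and wild-type libraries (17683 genes, 0.119), and the wild-type course used 8 libraries (17366 genes, 0.061). CPM values use TMM-scaled library sizes within each fit, so 1 library can have slightly different CPM in different fits. SE is the absolute log2 fold change over the square root of F. On simulated data with 200 genes changed in 2 against 2 libraries, log2 changes of 1 and -1 were called in 76% and 64% of cases in PS, 74% and 68% in RS and 90% and 85.7% in THY1. False calls there numbered 11, 16 and 3.

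X-linked genes and 20 gene lists were tested with camera from limma 3.58.1, at a preset correlation of 0.01 and with an estimated correlation. The lists were also tested with fry. With an estimated correlation camera relies on the few residual degrees of freedom of each fit. It then has little power, so a call lost there does not show that a shift is absent. Lists needed 5 tested members. Adjustment was over the 59 list and contrast pairs of the knockout comparisons, over 20 lists in each other contrast, and over 8 contrasts for the X chromosome. Classes and promoter targets were compared with Fisher's exact test (two-sided, in R), and over 10 strata of expression by the Mantel-Haenszel method. Lists against promoter peaks and the pairs of ubH2A peak lists used Fisher's exact test of SciPy 1.17.1. A promoter target is a gene with a peak within 1 kb of a transcription start site. Where a peak list carries the authors' own promoter assignment, the genes so assigned were taken instead. This holds for the crosslinked ubH2A list of GS cells, with 279 targets against 310 genes within 1 kb. Its alternative window was 1 kb, and that of SCML2, RNF2 and BMI1 was 3 kb. The 48 target tests and 200 list tests of promoter peaks were each adjusted together. Shares of peaks carry exact Clopper-Pearson 95% intervals, and medians in the closing section carry bootstrap intervals from 2000 resamples. Where all libraries of a group had 0 reads for a gene, its fold was replaced by a bound at a floor of 3 counts per library. Other tools were Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, DESeq2 1.42.0 and matplotlib 3.10.9.

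The main tests, the lists, the rule for named genes and most alternatives were fixed before the data were examined; the tests and alternatives chosen later are named below and in the closing section. The rule takes Scml2, then the 8 rising and 8 falling named genes with the smallest p among calls with an absolute log2 fold change of at least 1, a mean of at least 1 CPM and no overlap between the groups, then up to 3 called members of each list. Predicted or unnamed genes were skipped. For wild-type contrasts it takes called list members only, and for peaks the 5 promoter peaks of the highest fold per list and up to 3 target genes of each gene list. Genes called in PS and RS alike were ranked by their larger p, and 8 were taken.

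Alternatives were DESeq2, RLE factors, no filter or at least 1 CPM in 2 libraries, limma-trend on log2 of RPKM plus 0.5, an absolute log2 fold change of at least 1, each library left out in turn, each cell type fitted alone, THY1 fitted with all 12 libraries, the replicate number as a block, symbols at 1 locus only, another promoter window (3 kb), stronger peaks only, and removal of peaks that overlap input. A correction for GC content and transcript length by a loess offset (span 0.3), for the 99.0% of symbols found in the mm10 annotation, and thinning of the 8 PS and RS libraries to one depth were added after the data were seen, as were RLE factors for lists, the replicate block for the X chromosome, falling shared calls as a result of their own and the peak lists left out in turn. The input peak lists served as background only.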

Results

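RNA was sequenced from cultured germline stem cells (GS), THY1-positive spermatogonia (THY1), pachytene spermatocytes (PS) and round spermatids (RS), with 2 libraries per group. GS cells were wild type only; the other cell types came from wild-type mice and from mice labelled as Scml2 knockouts (KO). The series title names SCML2, a germline Polycomb protein encoded on the X chromosome, as the subject. The counted reads per library, in units of 1e6, were 17.48 and 15.94 for GS, 13.28 and 12.79 for THY1 wild type, and 14.1 and 15.8 for THY1 KO. They were 9.49 and 8.47 for PS wild type and 8.08 and 15.68 for RS wild type. The KO libraries were deeper, with 37.38 and 32.84 in PS and 36.28 and 36.43 in RS. The labels give the PS wild-type libraries the running numbers 343 and 363 and the RS wild-type libraries 99 and 100, while the 4 KO libraries of PS and RS run from 383 to 386. The THY1 libraries carry 1136 and 1137 in wild type and 1105 and 1107 in KO. If these numbers follow library batches, batch and genotype cannot be told apart in PS, RS or THY1. A further 14 libraries gave peak lists for SCML2, RNF2, BMI1 and ubiquitinated H2A (ubH2A) and for inputs.

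Scml2 itself (chromosome X, 161162772 to 161258213 in mm10) was highest in spermatogonia. It fell in the THY1 libraries labelled KO from 326 ± 38.8 to 47.9 ± 4.92 CPM (SD, n = 2; log2 -2.77 ± 0.12, SE; adjusted p = 1.19e-36). It fell in the RS libraries labelled KO from 25.1 ± 1.51 to 7.47 ± 0.33 CPM (log2 -1.75 ± 0.23; adjusted p = 0.000133). In PS no difference was called, at 9.49 ± 0.259 and 9.63 ± 3.41 CPM (log2 0.03 ± 0.23; adjusted p = 0.933), and the 2 KO libraries held 610 and 280 reads of the gene. The tables count reads per transcript and do not show which exons carried them, and the deleted part of the gene is not given in the sources used here.

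**Figure D1:**
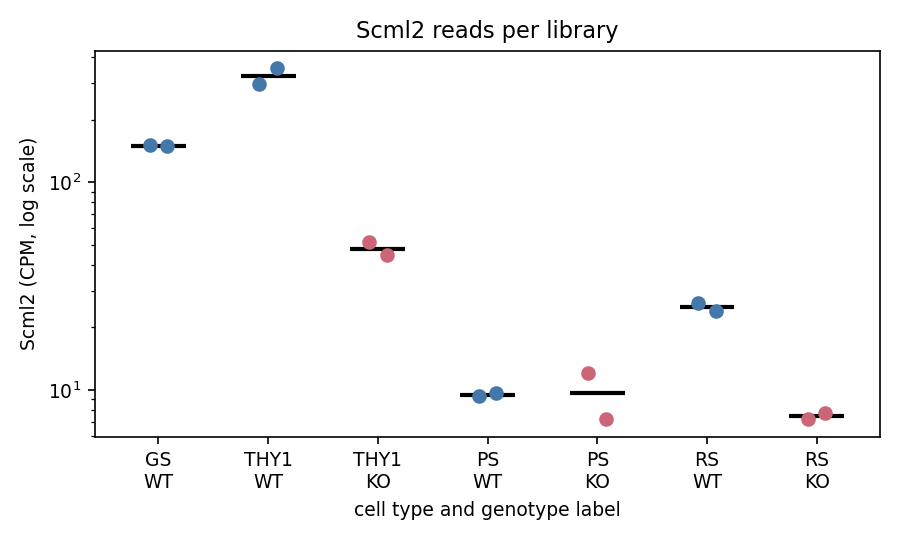
Scml2 reads as CPM (log axis) in each RNA library, by cell type and genotype; dots are libraries and bars their mean. GS libraries lie at 151 and 149 CPM, and the PS libraries labelled KO at 12 and 7.22 CPM, on both sides of the PS wild-type libraries at 9.31 and 9.67 CPM.

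The wild-type libraries trace the course of spermatogenesis, and they also hold reads of somatic marker genes. Leydig cell genes were higher in PS than in GS (13 of 13), as were 14 of 22 Sertoli cell genes, with 7 lower. The camera test called neither list (adjusted p = 0.0841 and 0.637). Against THY1, 10 of 13 Leydig cell genes were lower in PS. From GS to PS, all 41 round spermatid genes and 21 of 22 genes of pachytene and later spermatocytes rose, and 24 of 26 genes of undifferentiated spermatogonia fell. Ldhc, the testis lactate dehydrogenase, rose from 3.61 ± 0.109 to 5590 ± 165 CPM (SD, n = 2), and Ybx2, a germ cell RNA-binding protein, from 2.71 ± 0.253 to 3190 ± 221 CPM. Ret, the receptor of the stem cell factor GDNF, fell from 305 ± 17.2 to 0.662 ± 0.147 CPM. X-linked genes as a set fell: 489 of 721 were lower in PS than in GS and 173 higher, with a median log2 change of -2.71 against -0.05 for autosomal genes. Pgk1, a glycolytic enzyme of the X chromosome, fell by 6.98 ± 0.11 on the log2 scale and Huwe1, an X-linked ubiquitin ligase, by 4.30 ± 0.08.

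From PS to RS, 39 of 41 round spermatid genes rose further and 0 fell. Akap4, an X-linked sperm tail protein, rose from 620 ± 53.4 to 3280 ± 344 CPM (SD, n = 2) and Gapdhs, the sperm glyceraldehyde dehydrogenase, from 382 ± 4.63 to 1970 ± 218 CPM. Piwil1, a pachytene piRNA protein, fell by 4.34 ± 0.17 on the log2 scale and Mlh3, a crossover protein, by 3.12 ± 0.14. X-linked genes were higher in RS, with 367 of 721 called higher and 50 lower (median log2 1.24 against -0.03). Genes active in spermatids on the X and Y chromosomes rose (17 of 19), and germline genes that are methylated in soma fell (15 of 19, with 2 higher). Insl3, a Leydig cell hormone, fell by 5.45 ± 0.26 and 11 of 13 Leydig cell genes fell, while Dcn, a stromal proteoglycan, rose by 3.41 ± 0.32.

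Over all genes, 7441 rose and 7895 fell from GS to PS among 17366 tested, 7556 and 7812 from THY1 to PS, and 5443 and 5477 from PS to RS (edgeR, adjusted p below 0.05). Strain and isolation differ between GS and PS, and the THY1 libraries were deposited later. From PS to RS the choice of scaling moved the median of all genes to 0.23 with RLE factors, where 6664 genes rose and 4244 fell. The wild-type changes of the X-linked set passed limma's camera test (adjusted p = 3.78e-07 from GS to PS, 2.68e-08 from THY1 to PS and 7.45e-08 from PS to RS). With an estimated correlation each had adjusted p = 0.201. Counts adjusted over the list alone were the same for the lists named here. The pachytene list from GS to PS had adjusted p = 8.16e-17, and adjusted p = 0.0139 with an estimated correlation; for undifferentiated spermatogonia the values were adjusted p = 8.26e-07 and adjusted p = 0.158 with an estimated correlation. The round spermatid list had adjusted p = 3.34e-33 from GS to PS, and adjusted p = 0.0645 with an estimated correlation, and 1.65e-18 from PS to RS, and adjusted p = 0.178 with an estimated correlation. From PS to RS the lists of spermatid genes on X and Y, germline genes methylated in soma and Leydig cells had adjusted p = 1.68e-07, 8.87e-05 and 0.00266, and with an estimated correlation adjusted p = 0.178, 0.601 and 0.601.

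In pachytene spermatocytes labelled KO, the lists of spermatogonia and somatic testis cells and the X-linked set were called higher than in wild type, and that of pachytene and later spermatocytes lower. None of these calls held with an estimated correlation. The fry test called both spermatogonial lists and those of Sertoli, Leydig, stromal and pachytene cells (adjusted p of 0.0104 to 0.0458). It did not call the macrophage list (adjusted p = 0.121), and the X-linked set was not tested with fry. Kit, the receptor of differentiating spermatogonia, rose from 8 ± 0.658 to 34 ± 5.45 CPM (SD, n = 2), and Lin28a, an RNA-binding protein of stem cells, from 1.72 ± 0.384 to 10.6 ± 4.62 CPM. Hsd3b6, a steroid dehydrogenase of Leydig cells, rose from 6.28 ± 0.839 to 65.9 ± 8.81 CPM. Ccna1, the cyclin of the meiotic divisions, fell from 257 ± 17.7 to 77.9 ± 18.3 CPM. The comparison asks what differs in meiotic cells labelled KO, in which Scml2 itself was not called lower (log2 0.03 ± 0.23, SE).

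The rising genes of smallest p were Hsd3b6 (log2 3.39 ± 0.20, SE), Spint1, a protease inhibitor (3.90 ± 0.23), Fkbp10, a collagen chaperone (3.10 ± 0.18), Itgb4, an integrin of hemidesmosomes (4.04 ± 0.24), and Lcn2, an iron carrier (2.99 ± 0.19). Erbb2, a receptor kinase (4.41 ± 0.31), Fads2, a fatty acid desaturase (2.52 ± 0.18), and Abca1, a cholesterol exporter (2.90 ± 0.20), followed. Sptbn4, a spectrin, fell from 319 ± 9.84 to 22.7 ± 5.8 CPM (SD, n = 2; log2 -3.81 ± 0.18). Cyp2c55, a cytochrome P450 (log2 -5.46 ± 0.28), Ccdc7 (-3.19 ± 0.18), Cadm2, a cell adhesion molecule (-4.50 ± 0.27), and Epyc, a proteoglycan (-4.20 ± 0.26), fell too. So did Agtr1a, an angiotensin receptor (-2.64 ± 0.17), Mdga2, an adhesion molecule of neurons (-4.80 ± 0.33), and Pcdhga12 (-2.59 ± 0.17), whose cluster of protocadherins shares exons. All 16 had adjusted p of at most 7.67e-07.

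Among germ cell lists in PS, 14 of 23 genes of undifferentiated spermatogonia rose and 0 fell (median log2 1.45), and the count adjusted over the list alone was the same. Taf4b, a germ cell TFIID subunit, rose by 1.77 ± 0.22 and Sall4, a stem cell transcription factor, by 3.16 ± 0.47. Of 13 genes of differentiating spermatogonia, 11 rose and 2 fell, the same when adjusted over the list alone; Dnmt3a, a DNA methyltransferase, rose by 2.03 ± 0.26, and Dmrtb1, a factor of the entry into meiosis, fell by 1.31 ± 0.17. Of 30 meiotic prophase genes, 18 rose and 4 fell (18 and 5 adjusted over the list alone), with Tex15, a meiotic recombination factor, up by 1.21 ± 0.17. Of 22 genes of pachytene and later spermatocytes, 16 fell and 2 rose (17 and 2 adjusted over the list alone; median log2 -0.81), with Plk1, a kinase of cell division, at -0.98 ± 0.13 and Tbpl1, a TBP-like factor, at -1.07 ± 0.15. Of 41 round spermatid genes, 11 fell and 0 rose, also when adjusted over the list alone (median log2 -0.06), with Spata16, an acrosome protein, at -1.43 ± 0.17 and Catsper2, a sperm calcium channel subunit, at -1.10 ± 0.15. limma's camera gave adjusted p = 0.000807, 0.000603, 0.0272, 3.58e-06 and 0.013 for these 5 lists in this order. With an estimated correlation none held, at adjusted p = 0.546 for both spermatogonial lists and the pachytene list and adjusted p = 0.576 for the meiotic prophase and round spermatid lists. The meiotic prophase call was also lost with RLE factors (adjusted p = 0.0518) and the round spermatid call with the GC and length correction (adjusted p = 0.0649).

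Markers of somatic cells moved with the spermatogonial genes in the same PS libraries. Of 23 Sertoli cell genes 20 rose and 0 fell (median log2 1.71), of 13 Leydig cell genes 11 and 0 (2.47), of 20 genes of peritubular, stromal and endothelial cells 12 and 1 (1.44), and of 16 macrophage and leukocyte genes 10 and 0 (2.27). Adjusted over the list alone, the counts were the same except for macrophages, where 11 rose. Clu, a secreted protein abundant in Sertoli cells, rose from 131 ± 29.1 to 516 ± 175 CPM (SD, n = 2), Star, the cholesterol transporter of steroid synthesis, by 1.83 ± 0.16 on the log2 scale, Sparc, a matrix protein, by 2.19 ± 0.23, and Apoe, an apolipoprotein of macrophages, by 3.01 ± 0.33. The adjusted p of camera were 5.57e-07, 5.4e-11, 0.000219 and 0.00201. With an estimated correlation they were adjusted p = 0.546 for Sertoli, Leydig and stromal cells and adjusted p = 0.576 for macrophages.

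Of 16 genes of the p53 response and apoptosis, 11 rose and 2 fell in PS, the same when adjusted over the list alone (median log2 1.15; adjusted p = 0.00717, and adjusted p = 0.546 with an estimated correlation). Trp53inp1 rose by 1.43 ± 0.16 and Zmat3, an RNA-binding p53 target, fell by 2.42 ± 0.19. The PRC1 components, Polycomb proteins that ubiquitinate H2A, went both ways, with 13 of 24 higher and 6 lower (adjusted p = 0.0625); Cbx6 rose by 2.51 ± 0.25. Of 73 developmental transcription factors, 16 rose and 17 fell, with Sox17 at -3.14 ± 0.22 and Sox10 at 2.55 ± 0.28. Their median was 0.09, or 0.00 with Hoxd13 and Twist1 at their bounds, while camera's direction was down (adjusted p = 0.457). Of 22 factors of H2A ubiquitination and the sex body 7 rose and 5 fell (adjusted p = 0.604), with Usp22, a deubiquitinase, up by 1.61 ± 0.21. Of 28 mitotic cell cycle genes 11 rose and 10 fell (adjusted p = 0.689), with Mki67, a proliferation marker, up by 1.66 ± 0.13 and Bub1b, a spindle checkpoint kinase, at -1.09 ± 0.13. Of 19 germline genes methylated in soma 5 rose and 5 fell (adjusted p = 0.635), with Dazl, a germ cell RNA-binding protein, up by 1.32 ± 0.19. Adjusted over the list alone, the counts of these lists were the same.

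In PS 4923 genes were higher and 3995 lower in KO among 17287 tested, of which 3501 and 1141 had an absolute log2 change of at least 1. The 1141 were 732 without KO replicate 1 and 1844 without KO replicate 2. The balance depended on the method: RLE factors, a change of scaling alone, gave 4470 higher and 4603 lower, DESeq2 3859 and 4377, the GC and length correction 4324 and 4895, and limma on the deposited RPKM 7869 and 2007. The 2 PS libraries labelled KO had a chi-square over degrees of freedom of 44.6 against each other, and the other groups 1.47 to 11.8, with 11.5 for the RS libraries labelled KO, which are of like depth. Their correlation was 0.986, within the range of 0.985 to 0.995 over all groups. Some of the reported markers were higher in KO replicate 1 (Sall4 at 13.4 and 7.29 CPM, Taf1 at 32.1 and 19) and others in KO replicate 2 (Clu at 393 and 640 CPM).

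The X chromosome stood apart in PS. Of 714 X-linked genes 403 were higher in KO and 17 lower (56.4% higher, against 27.3% of 16537 autosomal genes), and the median log2 change was 1.26 against 0.08. Every autosome had a median between -0.03 (chromosome 18) and 0.16 (chromosome 19). Of 26 X-linked genes known to be silenced in meiosis, 23 rose and 0 fell, the same when adjusted over the list alone (median log2 1.56, or 1.42 with Ubl4a at its bound). Huwe1 rose from 38.2 ± 0.502 to 148 ± 40.3 CPM (SD, n = 2), Hprt, a purine salvage enzyme, by 3.43 ± 0.34 on the log2 scale, and Taf1, the large TFIID subunit, by 2.50 ± 0.27. Of 19 genes of the X and Y chromosomes active in spermatids, 3 rose and 0 fell, or 1 and 0 adjusted over the list alone (median log2 0.15; adjusted p = 0.817); Usp26, a ubiquitin protease, rose by 1.94 ± 0.29. camera called the X-linked set (adjusted p = 6.83e-11, and adjusted p = 0.231 with an estimated correlation) and the list of silenced genes (adjusted p = 5.38e-10, and adjusted p = 0.546 with an estimated correlation). Genes of 1 chromosome are not independent replicates.

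**Figure D2:**
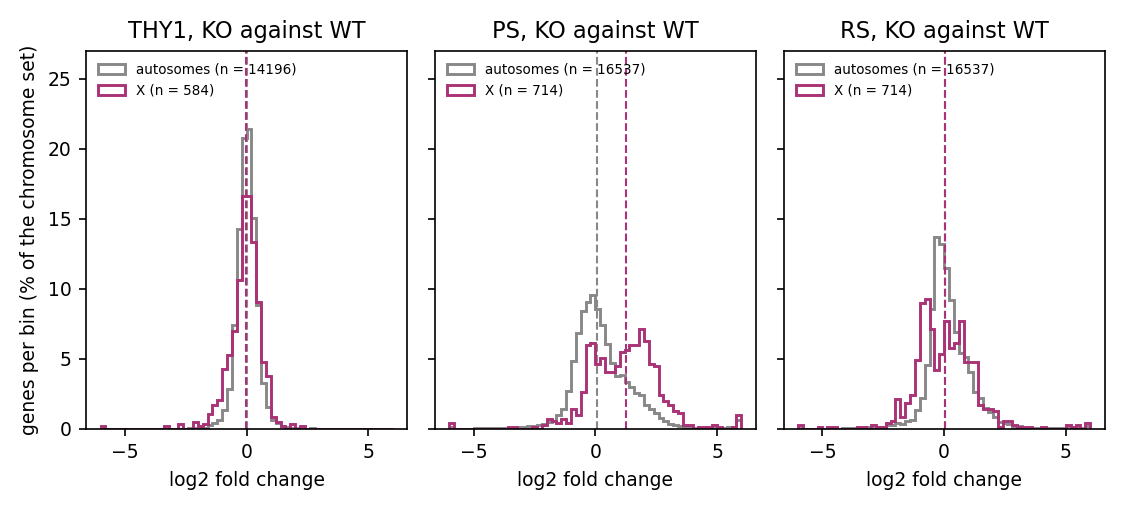
Distribution of log2 fold changes (KO over wild type, horizontal axis) of X-linked and autosomal genes in the KO comparisons, as percent of each chromosome set per bin, with values beyond the axis set to its ends; dashed lines are medians. In PS the X-linked median is 1.26 against 0.08 for autosomal genes, in RS 0.02 against 0.05, and in THY1 -0.00 against 0.02.

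In round spermatids labelled KO, the lists of round spermatids and of spermatid genes on X and Y were called lower, and those of macrophages, stroma and spermatogonia higher. None of these calls held with an estimated correlation, and most spermatogonial genes were not called. The fry test called both spermatid lists and those of stroma and undifferentiated spermatogonia (adjusted p of 0.0309 to 0.0496). It did not call those of macrophages (adjusted p = 0.0721) and differentiating spermatogonia (adjusted p = 0.137). Catsper1, a sperm calcium channel subunit, fell from 327 ± 10.6 to 160 ± 0.849 CPM (SD, n = 2), and Acrv1, an acrosome protein, from 467 ± 40.3 to 222 ± 1.71 CPM. Fkbp10 rose from 3.66 ± 0.126 to 70.1 ± 6.9 CPM and Mrc1, the mannose receptor of macrophages, from 2.69 ± 1.28 to 15.8 ± 3.3 CPM. The comparison asks what changes after meiosis where Scml2 is reduced.

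Fkbp10 (log2 4.25 ± 0.18, SE), Tas1r1, a taste receptor (6.78 ± 0.35, from 1 and 3 reads in the wild-type libraries), Spint1 (3.68 ± 0.21), Itgb4 (4.71 ± 0.27) and Zfp93, a zinc finger protein (4.74 ± 0.30), had the smallest p among rising genes. Tnxb, a matrix protein (3.81 ± 0.25), Aes, a corepressor (2.62 ± 0.17), and Erbb2 (4.71 ± 0.31) came next. Falling genes were led by Cyp2c55 (-4.18 ± 0.26), Mdga2 (-5.05 ± 0.31), Rassf9 (-3.02 ± 0.19), Cngb3, a channel subunit (-3.33 ± 0.21), and Acot10, a thioesterase (-3.06 ± 0.20). Aldoart1, a sperm aldolase, fell from 239 ± 0.681 to 49.8 ± 4.27 CPM (SD, n = 2), Adam26a, a testis metalloprotease, by 2.54 ± 0.17 and Ptchd3, a patched domain protein, by 3.36 ± 0.22. All 16 had adjusted p of at most 3.59e-07.

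Of 41 round spermatid genes 22 fell and 0 rose in RS (25 and 0 adjusted over the list alone; median log2 -0.46), with Spaca7, an acrosome protein, at -0.97 ± 0.14. Of 19 genes listed as active in spermatids on the X and Y chromosomes 12 fell and 0 rose (16 and 0 adjusted over the list alone, median log2 -0.87), with Cypt3 at -0.99 ± 0.18. Their adjusted p were 6.31e-09 and 3.16e-06, and with an estimated correlation adjusted p = 0.546 for both. With the GC and length correction the list of X and Y had 8 lower members and a median of -0.53. Of 22 genes of pachytene and later spermatocytes 6 fell and 0 rose (5 and 0 adjusted over the list alone; median log2 -0.32; adjusted p = 0.0431, adjusted p = 0.617 with an estimated correlation, and 0.0772 with the GC and length correction). Of 30 meiotic prophase genes 5 rose and 5 fell, or 6 and 5 adjusted over the list alone (median log2 0.24; adjusted p = 0.604); Rec8, a meiotic cohesin, was at -0.69 ± 0.13 and Mei1 at 1.49 ± 0.21. Of 23 genes of undifferentiated spermatogonia 9 rose and 0 fell (10 and 1 adjusted over the list alone; median log2 1.13; adjusted p = 0.00283, and adjusted p = 0.546 with an estimated correlation), among them Bcl6b, a stem cell repressor, at 2.13 ± 0.22. Of 13 genes of differentiating spermatogonia 5 rose and 1 fell (5 and 2 adjusted over the list alone; median log2 0.83; adjusted p = 0.0376, and adjusted p = 0.605 with an estimated correlation), with Ccnd1, a cyclin, at 1.56 ± 0.31. That call was lost with RLE factors (adjusted p = 0.0539) and the GC and length correction (adjusted p = 0.0902).

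Markers of other testis cells were higher in the same RS libraries. Of 16 macrophage and leukocyte genes 9 rose and 0 fell (12 and 0 adjusted over the list alone; median log2 1.76), of 20 peritubular, stromal and endothelial genes 11 and 1 (12 and 1; 1.06), of 13 Leydig cell genes 9 and 0 (10 and 0; 1.27, or 1.16 with Hsd17b3 and Lhcgr at their bounds), and of 23 Sertoli cell genes 8 and 0 (11 and 1; 0.93, or 0.86 with Fshr at its bound). Apoe rose from 22.1 ± 8.96 to 89.8 ± 12.8 CPM (SD, n = 2), Pdgfra, a stromal receptor, by 2.17 ± 0.34 on the log2 scale, Insl3 by 2.63 ± 0.37 and Espn, an actin bundler of Sertoli cells, by 1.23 ± 0.21. Their adjusted p were 5.86e-07, 0.000256, 0.0042 and 0.00614. With an estimated correlation they were adjusted p = 0.546 for macrophages and stroma, adjusted p = 0.573 for Leydig cells and adjusted p = 0.617 for Sertoli cells.

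Of 28 mitotic cell cycle genes 12 rose and 1 fell in RS (13 and 1 adjusted over the list alone; median log2 0.38; adjusted p = 0.00144, and adjusted p = 0.546 with an estimated correlation), with Mki67 up by 1.51 ± 0.14 and Gins1, a replication factor, by 1.34 ± 0.21. Of 16 genes of the p53 response and apoptosis 10 rose and 2 fell, the same when adjusted over the list alone (median log2 0.95; adjusted p = 0.00614, and adjusted p = 0.546 with an estimated correlation), with Cdkn1a, the p21 cell cycle inhibitor, up by 1.91 ± 0.28. Of 24 PRC1 components 9 rose and 2 fell (10 and 2 adjusted over the list alone; adjusted p = 0.0358, and adjusted p = 0.576 with an estimated correlation), with Yaf2 up by 1.59 ± 0.23; the call was lost with RLE factors (adjusted p = 0.0559) and the GC and length correction (adjusted p = 0.106). Of 22 factors of H2A ubiquitination and the sex body 4 rose and 5 fell, or 4 and 6 adjusted over the list alone (adjusted p = 0.663), with Ube2a, an X-linked ubiquitin-conjugating enzyme, at -1.26 ± 0.23. Of 73 developmental transcription factors 10 rose and 5 fell, or 6 and 4 adjusted over the list alone (adjusted p = 0.663), with Sox10 at 3.11 ± 0.24 and Pax9 at -3.22 ± 0.39. Of 19 germline genes methylated in soma 5 rose and 3 fell, the same when adjusted over the list alone (adjusted p = 0.635), with Dazl at 0.96 ± 0.19. Of 26 X-linked genes silenced in meiosis 9 rose and 1 fell, or 10 and 1 adjusted over the list alone (median log2 0.54; adjusted p = 0.0959), with Hprt at 1.32 ± 0.29 and Uba1, a ubiquitin-activating enzyme, at -1.08 ± 0.14.

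In RS 2750 genes were higher and 2661 lower in KO among 17287 tested. The balance depended on the method, with 2262 higher and 3649 lower with RLE factors, a change of scaling alone, 1858 and 3449 by DESeq2 and 2274 and 3531 with the GC and length correction, and limma on RPKM gave 4499 and 1062. Without 1 library the counts fell to 1363 and 1241 (without wild-type replicate 1), 1395 and 1422 (wild-type replicate 2), 1628 and 1282 (KO replicate 1) and 1398 and 1161 (KO replicate 2). X-linked genes showed no shift that camera called: 88 of 714 were higher and 186 lower, with a median log2 change of 0.02 against 0.05 for autosomal genes (adjusted p = 0.065). Without adjustment over contrasts, camera's p was below 0.05 for a shift down without wild-type replicate 1 (X minus autosome -0.08) and without KO replicate 1 (-0.09), and neither held with an estimated correlation (0.667 and 0.637).

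The effect of the KO label was tested for a difference between PS and RS, although Scml2 itself was lower in the RS libraries labelled KO and not in those of PS. X-linked genes rose in PS and showed no called shift in RS, and the effects differed: the median difference of log2 changes was -1.06 for 714 X-linked genes against -0.02 for autosomal genes, with 206 X-linked genes called lower in the difference and 0 higher (camera adjusted p = 7.04e-23, and adjusted p = 0.201 with an estimated correlation). Hprt differed by -2.12 ± 0.47 on the log2 scale and Rbbp7, an X-linked Polycomb partner, by -0.99 ± 0.31. Over all genes, 1028 had a higher and 1340 a lower effect in RS. This total of 2368 depends on single libraries: it was 387 without PS wild-type replicate 1, 1019 without PS wild-type replicate 2 and 5937 without PS KO replicate 2. It was 898, 739, 735 and 731 without RS wild-type replicates 1 and 2 and RS KO replicates 1 and 2.

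PS and RS shared many of their calls. Of the 4923 genes higher in PS, 2044 were also higher in RS, against 783.1 by chance (odds ratio 11.7, 95% interval 10.7 to 12.9, Fisher's exact test), and 1252 of the 3995 lower in PS were lower in RS, against 615 by chance (3.85, 3.53 to 4.2). The falling overlap had odds ratios of 2.06 (1.88 to 2.26) over expression strata, 6.15 with the GC and length correction and 14 at an absolute log2 change of at least 1, and the rising overlap 8.46, 11.2 and 17.8. Spint1, Fkbp10, Itgb4, Erbb2, 2610002J02Rik (log2 4.27 ± 0.29 in PS and 5.77 ± 0.32 in RS), Cyp2c55, Mdga2 and 1700010K23Rik (-4.21 ± 0.20 and -3.22 ± 0.19) led the shared calls. Genes at least 2-fold higher in GS than in RS wild type were over-represented among PS rises (3511 of 6404, 54.8% against 12.2% of other genes; odds ratio 8.77, 8.1 to 9.49). Genes higher in GS than in PS wild type were over-represented among RS rises (odds ratio 5.5, 5.02 to 6.05). Genes lower in GS were over-represented among falls, with odds ratios of 6.68 (6.16 to 7.24) in PS and 5.2 (4.74 to 5.71) in RS, or 4.16 and 3.36 over expression strata. The classes share no wild-type library with the comparison they are set against, and PS and RS share no library. Their KO libraries carry adjacent numbers, however, and all calls in PS and RS came from 1 joint fit. That fit shares the filter, the scaling and the estimate of spread of each gene. It also holds the PS and RS wild-type libraries that define the classes. The calls are thus not independent, while the values by chance and the odds ratios take them as such.

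In THY1 spermatogonia labelled KO, the lists of stromal, macrophage and Leydig cell genes were called higher and 5 germline lists lower. None of these calls held with an estimated correlation or with fry, and in 6 of these 8 lists at most 50% of the members were called. Myh11, the smooth muscle myosin, rose from 36.2 ± 0.742 to 148 ± 10.5 CPM (SD, n = 2) and Acta2, smooth muscle actin, from 273 ± 32.1 to 502 ± 32.3 CPM. Taf7l, a germ cell TFIID subunit on the X chromosome, fell from 428 ± 41.9 to 264 ± 12 CPM and Sox3, a factor of undifferentiated spermatogonia, from 154 ± 1.3 to 88.9 ± 20.7 CPM. The comparison asks what changes before meiosis where Scml2 is reduced.

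The smallest p among rising genes belonged to Myh11 (log2 2.03 ± 0.12, SE), Col12a1, a collagen (1.63 ± 0.12), Actg2, a smooth muscle actin (2.37 ± 0.18), Fat3, a protocadherin (2.19 ± 0.18), and Synpo2, an actin-binding protein of muscle (2.42 ± 0.21). Mylk, the myosin light chain kinase (1.33 ± 0.12), Agtr2, an angiotensin receptor (1.92 ± 0.17), and Cnn1, calponin of smooth muscle (1.90 ± 0.18), completed the 8. Omd, a proteoglycan, fell from 475 ± 67.6 to 151 ± 29.8 CPM (SD, n = 2; log2 -1.66 ± 0.11). Dclre1c, the Artemis nuclease (log2 -1.43 ± 0.11), Pet2, an X-linked gene (-2.14 ± 0.17), Tor4a (-1.41 ± 0.11), Ppm1k, a mitochondrial phosphatase (-1.35 ± 0.12), Mpv17l (-1.33 ± 0.12), Rin1, a Ras effector (-1.41 ± 0.12), and Pdha2, the testis pyruvate dehydrogenase subunit (from 26.1 ± 3.68 to 6.55 ± 1.13 CPM, SD), fell as well. All 16 had adjusted p of at most 1.99e-15.

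Of 20 peritubular, stromal and endothelial genes 10 rose and 0 fell in THY1 (12 and 0 adjusted over the list alone; median log2 0.31), of 16 macrophage and leukocyte genes 7 and 0 (10 and 0; 0.35), and of 12 Leydig cell genes 6 and 0 (6 and 0; 0.37). Their adjusted p were 1.63e-08, 0.000202 and 0.00144, and with an estimated correlation adjusted p = 0.546, 0.546 and 0.576. With the GC and length correction 7 stromal (median log2 0.20) and 12 macrophage genes (0.52) rose. Mrc1 rose by 0.84 ± 0.13 and Star by 0.67 ± 0.11. Of 21 Sertoli cell genes 4 rose and 0 fell, or 2 and 0 adjusted over the list alone (median log2 0.17; adjusted p = 0.0861, and adjusted p = 0.00534 with the GC and length correction, or 0.592 there with an estimated correlation), with Kitl, the ligand of Kit, up by 0.69 ± 0.11.

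Beside these markers, camera called 6 lists lower in the same THY1 libraries, those of germline genes and of the mitotic cell cycle. In most of these lists most members were not called. Of 19 germline genes methylated in soma 11 fell and 0 rose (14 and 0 adjusted over the list alone; median log2 -0.40), with Mael, a piRNA factor, at -0.62 ± 0.11 and Fkbp6, a chaperone of piRNA formation, at -0.67 ± 0.12. Of 26 genes of undifferentiated spermatogonia 7 fell and 1 rose (8 and 1 adjusted over the list alone; median log2 -0.19), with Pou5f1, a pluripotency factor, at -0.99 ± 0.15 and Utf1 at -1.66 ± 0.29. Of 28 mitotic cell cycle genes 8 fell and 0 rose (9 and 1; -0.18), with Gins1 at -0.81 ± 0.20. Of 29 meiotic prophase genes 7 fell and 2 rose (10 and 3; -0.24), of 16 pachytene genes 2 fell and 0 rose (2 and 0; -0.28) with Nxf2, an X-linked RNA export factor, at -0.74 ± 0.11, and of 5 spermatid genes of X and Y 3 fell and 0 rose (4 and 0; -0.75) with Fthl17 at -1.17 ± 0.21. The adjusted p of these 6 lists were 3.68e-07, 0.00274, 0.00506, 0.019, 0.0139 and 0.00299. With an estimated correlation they were adjusted p = 0.546 for germline and pachytene genes, adjusted p = 0.576 for undifferentiated spermatogonia, meiotic prophase and spermatid genes, and adjusted p = 0.633 for the cell cycle. With the GC and length correction 14 genes of undifferentiated spermatogonia (median log2 -0.33) and 4 pachytene genes fell.

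Lists that camera did not call in THY1 follow. Of 13 genes of differentiating spermatogonia 5 rose and 4 fell, or 6 and 4 adjusted over the list alone (adjusted p = 0.604), with Kit up by 0.95 ± 0.12 and Uchl1, a deubiquitinase of spermatogonia, at -0.66 ± 0.11. Of 76 developmental transcription factors 16 rose and 7 fell, or 16 and 8 adjusted over the list alone (median log2 -0.01; adjusted p = 0.194), with Hoxc8 at 2.61 ± 0.25, Tbx3 at 0.90 ± 0.13 and Gata2 at 0.98 ± 0.14. Of 25 X-linked genes silenced in meiosis 7 rose and 1 fell, the same when adjusted over the list alone (adjusted p = 0.0942), with Flna, an actin crosslinker, at 0.70 ± 0.11. Of 23 PRC1 components 4 rose and 5 fell (adjusted p = 0.817), with Phc3 at 0.62 ± 0.12, and of 17 p53 response genes 2 rose and 2 fell (adjusted p = 0.663), both the same when adjusted over the list alone. Of 22 factors of H2A ubiquitination and the sex body 1 rose and 2 fell, or 0 and 1 adjusted over the list alone (adjusted p = 0.381, and 0.00534 with the GC and length correction, or 0.662 there with an estimated correlation). Of 11 round spermatid genes 2 fell and 0 rose, the same when adjusted over the list alone (median log2 0.06, while camera's direction was down; adjusted p = 0.51), and Fabp9 had no read in either KO library.

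In THY1 2001 genes were higher and 1664 lower in KO among 14801 tested, and 1393 and 1808 with the GC and length correction. Fold changes followed transcript length across genes (r = 0.45 with log length, genes not being independent replicates). The counts were 1067 and 899 without wild-type replicate 1, 535 and 539 without wild-type replicate 2, and 613 and 550 with all 12 libraries in 1 fit. X-linked genes had 105 higher and 119 lower of 584, with a median of -0.00 against 0.02 (camera adjusted p = 0.338); without KO replicate 1 a shift down passed without adjustment over contrasts (X minus autosome -0.07), and it did not hold with an estimated correlation (0.15). The KO effect differed between PS and THY1 for 6149 of 17683 genes, of which 3878 were higher in PS, and the balance was 3029 and 3119 with DESeq2, 3268 and 3109 with RLE factors and 3151 and 3480 with the GC and length correction. X-linked genes had a median difference of 1.34 against 0.12 for autosomal genes (347 of 734 called higher and 13 lower; camera adjusted p = 4.28e-12, and adjusted p = 0.201 with an estimated correlation).

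**Figure D3:**
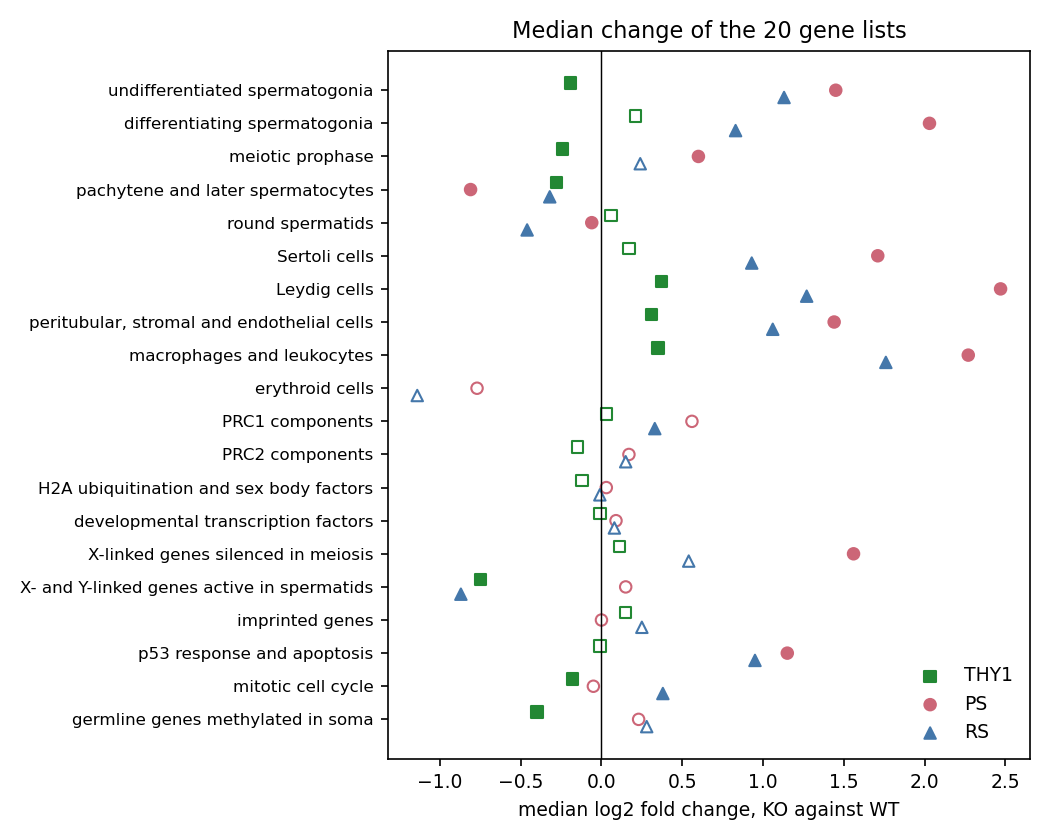
Median log2 fold change (KO over wild type) of each fixed gene list in PS, RS and THY1; filled points passed limma's camera test at a preset correlation, open points did not. Leydig cell genes reach 2.47 in PS and genes of pachytene and later spermatocytes lie at -0.81 there, while the medians of THY1 stay between -0.75 and 0.37.

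The peak lists place SCML2 and the PRC1 proteins RNF2, the catalytic subunit, and BMI1 at promoters of GS cells, with 1 library each and no replicate. SCML2 had 7491 peaks, of which 50.9% lay within 1 kb of a transcription start site (95% interval 49.76 to 52.04), at 3724 genes. RNF2 had 17153 peaks (55.1% at start sites, 8381 genes) and BMI1 3415 (30.5%, 844 genes). The highest SCML2 promoter peaks outside input signal lay at Ttc14 (chromosome 3, 33800138 to 33800516 in mm10; fold 11.75), Eya1, a developmental phosphatase (chromosome 1, 14309666 to 14310067; 8.73), and Hif1a, the hypoxia factor (chromosome 12, 73908457 to 73908810; 8.02). RNF2 had a peak at Ttc14 (18.4), and BMI1 at the shared promoter of Cyp24a1 and Pfdn4 (14.67), at Ttc14 (13.58) and at Tlx2, a homeobox gene (12.15). Peaks at Mir466d and Dux overlapped input peaks.

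Promoters with SCML2 were also promoters with RNF2: 2808 of 3724 targets (75.4%, against 28.2% of other genes; odds ratio 7.8, 7.19 to 8.46, Fisher's exact test; 4.65 with stronger peaks only and 4.66 over expression strata). SCML2 targets shared 427 genes with BMI1 (odds ratio 6, 5.21 to 6.92). They shared 102 with crosslinked ubH2A, whose targets are the authors' promoter assignments (3.11, 2.41 to 4.01). That value was 1.07 with stronger peaks only, which did not pass. With windows of 3 kb for SCML2 and 1 kb for ubH2A, 144 genes were shared (4.22, 3.35 to 5.33). RNF2 was at 808 of 844 BMI1 targets (44.6, 31.9 to 64.2; 9.18, 7.54 to 11.2, with stronger peaks only). SCML2 targets had a median of 19.5 CPM in GS cells against 1.83 for other genes, and RNF2 targets 19.9 against 0.443. BMI1 and ubH2A targets were low, at 0.811 against 4.04 and 0.479 against 3.84 CPM.

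Of 124 developmental transcription factors, 95 had an RNF2 promoter peak (76.6%, against 35.7% of all genes), 47 a BMI1 peak (odds ratio 17.3), 33 a peak in the crosslinked ubH2A list (34.1) and 40 an SCML2 peak (2.54). The other ubH2A list of GS cells, made after MNase digestion, had a promoter peak at 0 of the 124. It held 495 peaks, of which 34.7% overlapped input peaks. All ubH2A targets of GS cells given here are of the crosslinked list. Hoxd3 had an RNF2 peak (fold 5.78), and Nkx6-2 and Evx1, homeobox genes, had BMI1 peaks (5.98 and 5.22) and ubH2A peaks (7.46 and 7.1). Among 19 germline genes methylated in soma 14 had an RNF2 peak (adjusted p = 0.0357 over 200 Fisher's exact tests), with folds of 8.47 at Mael, 8.19 at Stk31 and 7.43 at Fkbp6. Among 21 genes of X and Y active in spermatids 0 had one (adjusted p = 0.00488, Fisher's exact test). RNF2 peaks were few on these chromosomes, with 190 of 17153 on X (1.11%) and 8 on Y. Of 26 X-linked genes silenced in meiosis, 3 had an RNF2 peak (11.5%). The lack is thus not shown to be particular to spermatid genes.

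SCML2 targets were called higher in THY1 KO more often than other genes (755 of 3210, 23.5% against 10.7%; odds ratio 2.55, 2.31 to 2.83; adjusted p = 1.96e-68 over 48 Fisher's exact tests) and lower less often (161, 5.02% against 13%; 0.354, 0.298 to 0.419). After the GC and length correction the values were 1.92 for higher and 0.69 (0.604 to 0.787; 9.4% against 13.1%) for lower calls, and the lower value was 0.215 without wild-type replicate 2. RNF2 targets (1.41, 1.28 to 1.55), BMI1 targets (2.24, 1.8 to 2.77) and ubH2A targets (1.71, 1.1 to 2.58) were also called higher more often in THY1. Over expression strata the value for BMI1 was 3.45 (2.76 to 4.3) and for ubH2A 2.81 (1.84 to 4.29), against 2.33 for SCML2 and 1.22 for RNF2. All of these tests count genes, not libraries, as units. In PS and RS the odds ratios for higher calls were 1.21 (1.11 to 1.31) and 1.17 (1.05 to 1.29) for SCML2, and 1.23 (1.15 to 1.31) and 1.33 (1.22 to 1.44) for RNF2. RNF2 targets were also called lower more often in PS (1.18, 1.1 to 1.27, but 0.952 over expression strata, which did not pass) and less often in RS (0.679, 0.623 to 0.74). BMI1 targets were called higher less often in PS (0.81, 0.661 to 0.988, adjusted p = 0.0485, Fisher's exact test) and showed no difference in higher calls in RS (0.941, 0.734 to 1.19). Over expression strata BMI1 targets were called lower more often, at 1.95 (1.55 to 2.44) in PS and 1.75 (1.38 to 2.22) in RS. Without strata these values were 0.987 and 1.14, which did not pass. For higher calls ubH2A targets had 0.748 (0.511 to 1.07) in PS and 1.48 (1 to 2.15, adjusted p = 0.0491, Fisher's exact test) in RS. With stronger peaks only the SCML2 value in RS was 1.08 and the BMI1 value in PS 0.903, and neither passed. The BMI1 value in PS was 0.891 after thinning, and the ubH2A value in RS 1.12 after the GC and length correction, and neither of these passed.

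**Figure D4:**
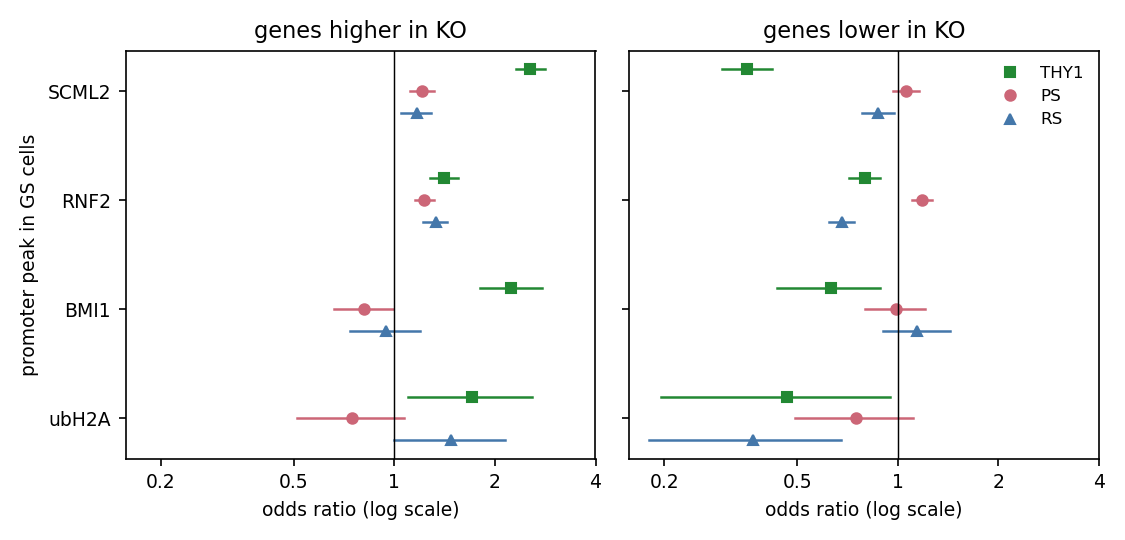
Odds ratio (log axis, with 95% interval) that a promoter target in GS cells of SCML2, RNF2, BMI1 or ubH2A is called higher in KO, against other tested genes, in PS, RS and THY1. The SCML2 value in THY1 is 2.55, against 1.21 in PS and 1.17 in RS.

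For ubH2A in PS there were 2 wild-type and 2 KO peak lists after MNase digestion. They differed as much within a genotype as between: wild type had 200 and 716 peaks and KO 63 and 798. The X-linked share of peaks was 3% (95% interval 1.11 to 6.42) and 1.12% (0.484 to 2.19) in wild type and 4.76% (0.993 to 13.3) and 1.63% (0.87 to 2.77) in KO. Within the pairs of the same replicate number Fisher's exact test gave p = 0.451 and p = 0.511. Peaks on autosomes averaged 446 in wild type and 420 in KO. No test between the 2 pairs of lists was run. Input peaks overlapped 71 and 120 of the wild-type peaks (35.5% and 16.8%) and 55 and 153 of the KO peaks (87.3% and 19.2%). The highest promoter peak outside input signal lay in both wild-type lists at the shared promoter of 3110070M22Rik and Gm7120 (fold 7.31 and 5.79), which also had a peak in KO replicate 2 (6.55). Below it came M1ap, a meiosis factor (6.18), in wild-type replicate 1, and Epha6, an ephrin receptor (5.52), and Tuba1a, a tubulin (5.37), in wild-type replicate 2. The wild-type SCML2 list in PS had 258 peaks, of which 84.5% overlapped input peaks, so it was not used for targets.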

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

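The tests of implied cell shares on X-linked genes, of GC content and length on the spermatogonial list, and of the spermatogonial list against the pooled Sertoli, Leydig, stromal and macrophage lists were chosen only after the result was seen. The results here were singled out because the KO effect differed between cell types by a test of the difference itself (edgeR for genes, limma's camera for lists and the X chromosome).

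Between RS and PS (RS minus PS), the X minus autosome median of the KO effect was -1.04 and 2368 genes differed, a count that fell to 387 without PS wild-type replicate 1 and to 1019 without PS wild-type replicate 2. It was 898 and 739 without RS wild-type replicates 1 and 2, 735 and 731 without RS KO replicates 1 and 2, and 5937 without PS KO replicate 2. The list medians were -1.27 for X-linked genes silenced in meiosis (0 members called higher and 15 lower), -0.89 for spermatid genes of X and Y (0 and 8), -1.14 for differentiating spermatogonia (1 and 3), -0.46 for meiotic prophase (0 and 6) and -0.77 for Sertoli cells (0 and 4). They were 0.46 for pachytene and later spermatocytes (6 and 1), -0.30 for round spermatids (3 and 14) and 0.34 for the mitotic cell cycle (7 and 2). Of the genes named in both cell types, Cyp2c55 differed by 1.29, Fkbp10 by 1.15, Sox17 by 1.24, Hprt by -2.12, Rbbp7 by -0.99 and Scml2 by -1.77 on the log2 scale.

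Between PS and THY1 (PS minus THY1), the X minus autosome median was 1.21 and 6149 genes differed. The list medians were 1.46 for X-linked genes silenced in meiosis, 1.71 for undifferentiated and 1.75 for differentiating spermatogonia, 0.79 for meiotic prophase, 1.38 for Sertoli cells, 2.13 for Leydig cells, 0.90 for stromal cells, 2.14 for macrophages, 1.13 for the p53 response and 0.50 for germline genes methylated in soma. Taf7l differed by 2.83, Scml2 by 2.77, Fkbp6 by 1.76, Usp3 by 1.76, 1700013H16Rik by 1.21, Star by 1.13, Kit by 1.10, Mrc1 by 1.01, Phf1 by -0.70 and Dmrtb1 by -2.36 on the log2 scale. The list calls of both differences were lost with an estimated correlation.

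X-linked genes lay higher than autosomal genes in the PS libraries labelled KO. Autosomal genes matched on the wild-type ratio of GS to PS rose by a median of 0.81 while X-linked genes rose by 0.91, and the excess of X-linked genes was 0.20 (95% interval 0.11 to 0.28), or 0.07 (0.01 to 0.20) for 74 X-linked genes of at least 10 CPM; matched on THY1 at that level it was 0.13 (0.04 to 0.29), and on RS 0.41 (0.35 to 0.50), and with the wild-type libraries in swapped roles these 4 values were 0.34, 0.31, 0.39 and 0.56. Version 3 of the test compared the cell shares that X-linked and autosomal genes would need, after the CPM minimum was seen to drop most silenced genes, and gave ratios of 1.65 (1.47 to 1.83) for GS and 1.28 (1.16 to 1.43) for THY1. Matched on THY1 with no CPM minimum the excess was 0.14 (0.07 to 0.21). The medians there were 1.03 for X-linked and 1.04 for autosomal genes. All excesses and ratios kept their side with the wild-type roles swapped. They argue against a gain of GS-like, THY1-like or spermatid cells, each taken alone, as the whole cause. The intervals resample genes and hold no spread between libraries, and the 4 swapped values lay outside them. Noise in the matched ratio can raise such an excess, and a mix of cell types was not tested. Cells of early meiosis, for which this series holds no library, a difference between library batches, if KO and wild type were prepared apart, which the labels do not say, and weaker silencing of the X chromosome in KO stay open.

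Of 23 genes of undifferentiated spermatogonia 14 rose in the same PS libraries and 9 were not called. The camera call of this list was lost with an estimated correlation (adjusted p = 0.546). The rise was kept after the correction for GC content and length (median log2 1.25, 95% interval 1.10 to 2.22), which argues against those trends, and it did not differ from that of the pooled somatic lists (median difference -0.39, -0.76 to 0.25), which leaves a lower share of spermatocytes open. Whether every other type rose alike is not settled. Of 9 erythroid genes 1 rose and 2 fell (median -0.77, mean 0.06, not called as a list). Single genes differed in direction between the 2 KO libraries, with 13.9 and 7.35 CPM of Lin28a against 393 and 640 of Clu. A gain of cells with a GS profile may also explain the rise of the list. The 985 abundant autosomal GS genes needed a median share of 6.65% and 20 listed genes 5.13%, a ratio of 1.3 (0.647 to 3.51). A batch difference, if KO and wild type were prepared apart, and a change of expression within spermatocytes stay open.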

How the results depend on the processing

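The GC and length correction, thinning, RLE factors for lists, the replicate block for the X chromosome, falling shared calls as a result of their own, and the peak lists left out in turn were chosen after seeing the data. Over the results that answer a comparison, 228 values under alternatives kept their side of the threshold or stayed near the reported value, 42 values without a test moved further, 6 calls were lost and 5 gained, 4 of them X-linked shifts without adjustment over contrasts. No called result changed direction, while the untested ubH2A differences between KO and wild type changed sign under some alternatives. The cause was not tested for the others, except that leaving out a library or asking for a log2 change of at least 1 leaves fewer data or calls by construction; a lone library is assumed to vary like the other groups.

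limma on RPKM gave 7869 higher and 2007 lower genes in PS, 4499 and 1062 in RS and 1241 higher in THY1, and DESeq2 1275 higher in THY1. With an absolute log2 change of at least 1, 1141 genes were lower in PS (732 and 1844 without KO replicates 1 and 2), 1700 higher and 681 lower in RS, 196 and 215 in THY1 and 3218 lower from PS to RS, and 1255 and 3973 genes differed between PS and RS and between PS and THY1. With all 12 libraries THY1 had 613 and 550. Without single libraries the counts ranged from 1363 to 1628 higher and 1161 to 1422 lower in RS (main 2750 and 2661), from 535 to 2343 and 539 to 1977 in THY1, and from 387 to 5937 for the difference between PS and RS. The lowest THY1 counts came without wild-type replicate 2, and without wild-type replicate 1 they were 1067 and 899.

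The X minus autosome median in PS was 0.93 to 1.35 without single libraries, and 1.18 but no longer called with an estimated correlation. In RS it passed without adjustment at -0.03 with the replicate block (not with an estimated correlation, 0.704) and ranged from -0.09 to -0.06 without single libraries, and in THY1 from -0.07 to 0.02. Of 59 list tests 32 were called and 0 with an estimated correlation, while fry, another test, called 18. All calls of fry were in PS or RS. In THY1 fry called no list, with adjusted p = 0.125 for stromal genes and 0.105 for germline genes methylated in soma. Lists were not rerun without single libraries. The replicate block gave 4737 and 3798 genes in PS, 2631 and 2305 in RS, 1976 and 1654 in THY1 and 32 lists, and deviations of equal replicate numbers correlated at -0.09, -0.06 and 0.08.

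With stronger peaks only, odds ratios of 1.08 (SCML2 in RS), 0.903 (BMI1 in PS) and 1.07 (overlap of SCML2 and ubH2A) no longer passed, nor did 0.891 for BMI1 in PS after thinning and 1.12 for ubH2A in RS after the GC and length correction; ubH2A in PS passed over strata at 0.618. The X share of ubH2A peaks (KO minus wild type, 1.14 points) was -0.491 without input overlap, -0.488 with overlap of 50% of the peak, and -0.43 to 2.7 without single lists, and the difference in autosomal peaks was -386 to 334.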

Other observations

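The stratified test of SCML2 targets was chosen only after the result was seen, and this pattern was picked after its odds ratio was known.

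Imprinted genes, PRC2 components and erythroid genes were not called as lists by camera in any KO comparison, apart from PRC2 components in THY1 after the GC and length correction. Igf2, a growth factor, rose by 3.30 ± 0.32 (log2, SE) in PS and by 2.60 ± 0.30 in RS, Igf2r by 1.77 ± 0.23 in PS and Impact by 1.79 ± 0.36 in RS, while Slc22a18 fell by 1.22 ± 0.17 in PS and Cdkn1c, a cell cycle inhibitor, by 0.90 ± 0.14 in THY1. As a list, 6 of 24 imprinted genes rose and 5 fell in PS (adjusted p = 0.791), 7 and 3 in RS (adjusted p = 0.13) and 5 and 3 in THY1 (7 and 3 adjusted over the list alone; adjusted p = 0.607). Of 11 PRC2 components 4 rose and 2 fell in PS (adjusted p = 0.409), 2 and 0 in RS (adjusted p = 0.203) and 1 and 2 in THY1 (adjusted p = 0.293, and 0.0297 with the GC and length correction, where 5 fell, or 0.662 there with an estimated correlation); Rbbp7, which is X-linked, rose by 2.63 ± 0.23 in PS and by 1.64 ± 0.21 in RS, and Phf1 fell by 1.11 ± 0.17 in PS. Of 9 erythroid genes 1 rose and 2 fell in PS (adjusted p = 0.291) and 0 and 4 in RS (0 and 6 adjusted over the list alone; adjusted p = 0.0659), and fewer than 5 were tested in THY1. Elsewhere the counts adjusted over the list alone were the same.

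Promoter targets of SCML2 in GS cells were called higher more often in the THY1 libraries labelled KO, the hypothesis being a loss of repression by SCML2. The odds ratio of 2.55 was 1.92 (95% interval 1.7 to 2.17) after the GC and length correction, 2.33 (2.1 to 2.58) over strata of expression and 2.54 (2.23 to 2.9) within genes with an RNF2 peak. These values argue against length, expression level or RNF2 promoters, each taken alone, as the whole cause. They were not tested together, and the values over strata and within RNF2 genes carry no length correction. The rise was not particular to SCML2, since over strata BMI1 and ubH2A targets had 3.45 and 2.81. It was also small, with a median log2 change of 0.15 for SCML2 targets against -0.02 for other genes. A change in the cell mix of the THY1 fraction, where stromal and macrophage genes rose, stays open and was not tested. The same holds for the use of peaks from another cell source. A difference between library batches, if KO and wild type were prepared apart, stays open too.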
